A study of Mus musculus with 8 samples.

How the data were processed

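RNA was measured by sequencing in 8 libraries of lateral ganglionic eminence from mouse embryos at E12.5, 4 labelled wild type and 4 labelled null for Gsx2. Per the labels' protocols, embryos came from crosses of heterozygous carriers of the alleles Gsx2RA and Gsx2EGFP and were genotyped from tail tissue. Polyadenylated RNA was isolated, stranded libraries were made with a dUTP method and 9 PCR cycles, and single-end reads of 51 bp were sequenced, per the labels' protocols. Per the submitters' processing notes, the tools were STAR (alignment), featureCounts (counting) and edgeR, with the genome build mm10; their versions, the annotation, and whether the counting used strand are not given in the sources used here.

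The authors deposited 1 table of 12843 genes. Per the file headers it holds the RPKM of each library, and the values themselves show neither a log scale nor an added constant. It also holds the authors' log2 fold change and average log2 CPM, per the file headers, and a p-value and an FDR for each gene, which the authors computed with edgeR per the submitters' processing notes. The authors' log2 fold change is positive where the null-labelled libraries are higher, which was checked against the RPKM of 1782 genes with an absolute value above 0.5 (100% had the same sign). The deposited FDR equals a Benjamini-Hochberg adjustment of the deposited p-value over the listed genes, with a largest gap of 1.55e-15. Every listed gene reached an RPKM of 0.5 or more in at least 1 library, 0 listed genes matched chromosome Y or the mitochondrial genome and 2 matched chromosome X (Mir1906-2 and Gm5643), so genes of these chromosomes, list members on chromosome X among them, were in effect not analysed here. Genes low in all libraries are therefore outside every count given here.

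Column names gave each library's group, as WT or Germline, and a number that is in no label. Germline was read as null for Gsx2 because the series title names the germline knock-out. Columns were therefore assigned to genotypes and not to single samples, and 0 columns were left out. The design had foreseen read counts. As the table holds RPKM, the test set out for that case was used: log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with genotype as the term and an intensity trend in the empirical Bayes step, two-sided, with Benjamini-Hochberg adjustment over all genes tested. Genes with a mean RPKM of at least 1 in either genotype were tested (11395), and 1448 were not. Every adjusted p of a gene is from this limma fit, unless the text names another fit, scaling or set of libraries. Every adjusted p of a list is from limma's camera or fry, and the threshold was 0.05. A pseudocount of 1 shrinks the fold changes of genes with low RPKM.

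RPKM values of a gene are whole multiples of the value of 1 read in each library, and these steps gave whole reads for 100% of listed genes. The tolerance was 1e-06 of a read, widened in proportion for genes with many reads. For 44 genes a common factor was restored from the authors' average log2 CPM, and the recovered reads differed from that average by a median of 0.0031 on the log2 scale. Recovered reads in listed genes ran from 16031458 to 18019214 per library. They set the depth and entered 1 alternative fit (limma voom), never the main result. To look for a library deposited more than once, the reads of libraries of the same genotype were compared: pairs had a chi-square per degree of freedom of 3.68 to 12.7 over genes, so none agreed within sampling noise, and Pearson correlations of 0.989 to 0.995 across genes, which are not independent replicates.

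Before the data were examined, 28 gene lists were fixed for regions, cell types, cell states, pathways, sample quality and the neighbourhood of Gsx2. Lists with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. With an estimated correlation 0 of 25 lists passed camera (5 at an unadjusted p under 0.05). The rule for named genes, fixed at the same time, was Gsx2; the 12 largest rises and the 12 largest falls among genes past the threshold with an average log2 CPM of at least 1 and no overlap between genotypes, passing over gene models without a name (85 passed over); up to 4 members of each list with the smallest adjusted p, or the 2 with the highest expression where none passed; and all sex-linked genes. Chosen after their values were seen were Gm19583 and these further list members: Bcl11b, Ccnd1, Chic2, Clock, Dlx6, Ebf1, Emx1, Etv1, Foxp2, Gsx1, Hes5, Isl1, Mki67, Nefl, Nefm, Neurod6, Pax6, Ppp1r1b, Ptch1, Rarb, Reln, Scfd2, Srd5a3, Tbr1, Tfap2c, Tmem165, Trp73, Tshz1, Usp46 and Wnt7b, and, named for their calls under other scalings, Axin2, Btg2, Cdk4, Esam, Notch3, Nrarp, Ptn and Sox9. Some listed genes are in more than 1 list: Rarb and Rxrg in the striatal and the retinoid list, Foxp2 and Meis2 in the striatal and the dorsal LGE list, Kdr in the endothelial and neighbour lists, Pdgfra in the oligodendrocyte and neighbour lists, Lef1, Wnt7b and Sfrp2 in the pallial progenitor and Wnt lists, and Gli3 in the pallial progenitor and Hedgehog lists. Some genes that the rule names or that are list members are not reported here by name, though they enter the counts and tests.

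Gene positions are from GENCODE M21 (GRCm38, the same build as mm10), matched by symbol for 12593 genes and by an older symbol for 165, with 85 not matched. The fit was tested on simulated data in which 200 genes were changed and 11254 genes in all passed the filter and were tested, made with the median dispersion of these libraries (0.00299) and so with less spread than many real genes have. In that simulation of null-labelled against wild type it called 62% of genes changed 1.25 times, 98% of those changed 1.5 times, 100% of those changed 2 or 4 times and 0.0995% of unchanged genes. A simulated list of 25 raised genes passed camera with either correlation (3.68e-05 with an estimated correlation), and 0 of 40 unchanged lists passed. No correlation between genes was put into this simulation. In the real lists the estimated correlation ran from -0.0136 (dorsal LGE) to 0.712 (subpallial GABAergic genes). The 0 of 40 therefore does not show how often camera passes unchanged lists of correlated genes. The alternatives were 3 other scalings, voom on recovered reads, a robust fit, other filters and pseudocounts, a fit without haemoglobin genes, a test against a log2 fold change of 0.5 (limma treat), each library left out, and, chosen after seeing the data, library numbers 1 to 6 against 7 to 12 as a covariate or as subsets and a filter at 5 RPKM. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.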

Results

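The deposited table covered the lateral ganglionic eminence (LGE), the part of the embryonic ventral forebrain that gives rise to the striatum and to olfactory bulb interneurons, dissected from mouse embryos at E12.5 (embryonic day). There were 4 libraries labelled wild type and 4 labelled null for Gsx2, a homeobox transcription factor of LGE progenitors; the null genotype combined the alleles named Gsx2EGFP and Gsx2RA. Each library held between 16031458 and 18019214 reads in the 12843 listed genes, with 16031458 to 17512880 in the wild-type and 16066545 to 18019214 in the null-labelled libraries. The comparison asked which RNAs differ in the LGE when Gsx2 is mutated. Levels are RPKM (reads per kilobase of gene, scaled to library size), given as mean ± SD over 4 libraries per genotype. Log2 fold changes are null-labelled minus wild type, with their standard error (SE), on the scale of log2(RPKM + 1), which understates the change of genes with low RPKM. The labels do not say whether a library came from 1 embryo or several, so p-values measure only the spread between these samples. Libraries are named by the number in their column names, which is in no label and is not the replicate number of the titles.

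Gsx2 RNA was higher in the libraries labelled null. Its RPKM was 22.1, 21.4, 26.0 and 24.6 in wild-type libraries 1, 2, 7 and 8, and 50.04, 49.1, 57.6 and 64.2 in null-labelled libraries 5, 6, 11 and 12. The means were 23.5 ± 2.16 and 55.2 ± 7.11 (SD, n = 4 each), a log2 fold change of 1.19 ± 0.09 (SE, adjusted p = 2.00e-05), with all 4 null-labelled libraries above all 4 wild-type libraries. Gsx2 (ENSMUSG00000035946.7) lies on chromosome 5 from 75075601 to 75077893 in GRCm38. Which part of the gene the alleles keep is not given in the sources used here, so RNA summed over the gene cannot check the genotype labels, and directions below refer to libraries as labelled.

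Of 11395 genes tested, 3242 (28.5%) passed an adjusted p of 0.05, 1574 higher and 1668 lower in the null-labelled libraries. An absolute log2 fold change of at least 1 was reached by 208 of them, 133 higher and 75 lower. The median absolute log2 fold change of the genes past the threshold was 0.32. The 2 genotypes did not overlap in 30.9% of tested genes, against 2.86% expected for a gene if all splits into 4 and 4 were equally likely. Genes are not independent of each other, so this share does not exclude chance. The count of 208 depended on the pseudocount, with 363 genes at a pseudocount of 0.1 and 85 at 5. Within libraries 1, 2, 5 and 6 alone 1949 genes passed (38.6% higher), and within libraries 7, 8, 11 and 12 alone 2966 passed (64.5% higher), against 48.6% higher in all 8 libraries. The first principal component of the log2 values held 60.8% of the variance and separated the genotypes, and the next held 14.4% and separated null-labelled libraries 5 and 6 from 11 and 12.

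The largest rise on the log2(RPKM + 1) scale among the genes the naming rule took was that of Pdgfra, the alpha receptor of platelet-derived growth factor. Pdgfra rose from 0.520 ± 0.0430 to 34.1 ± 4.13 RPKM (log2 fold change 4.52 ± 0.08, adjusted p = 7.46e-10). Dbx1, a homeobox gene of the ventral pallium and septum, rose from 0.415 ± 0.432 to 15.4 ± 3.42 RPKM (3.56 ± 0.21, adjusted p = 3.66e-06). Neurog1 (2.86 ± 0.24), Eomes (2.74 ± 0.47), Uncx (2.72 ± 0.17), Lhx9 (2.68 ± 0.20), Neurog2 (2.56 ± 0.42), Barhl2 (2.41 ± 0.23), Nhlh1 (2.37 ± 0.34) and Nhlh2 (2.24 ± 0.26), all transcription factors, rose as well. Slc17a6, a vesicular glutamate transporter, rose by a log2 fold change of 2.25 ± 0.32, and Nrn1, the secreted neurite-growth factor neuritin, by 2.25 ± 0.30.

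The largest falls on the same scale were those of the Dlx homeobox genes Dlx1 and Dlx2. Dlx1 dropped from 173 ± 11.3 to 16.1 ± 4.35 RPKM (log2 fold change -3.38 ± 0.15, adjusted p = 8.08e-07) and Dlx2 from 137 ± 19.7 to 13.5 ± 4.60 RPKM (-3.31 ± 0.20, adjusted p = 5.32e-06). Slc18a2, the vesicular monoamine transporter, dropped from 39.5 ± 3.94 to 4.60 ± 0.785 RPKM (-2.86 ± 0.10). Sp8 and Sp9, zinc finger factors of LGE-derived interneurons and striatal neurons, had log2 fold changes of -2.62 ± 0.06 and -2.60 ± 0.21. Grik3, a kainate receptor subunit (-2.56 ± 0.11), and Gucy1a3, a subunit of soluble guanylate cyclase (-2.46 ± 0.13), were also among the 12 largest falls.

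**Figure D1:**
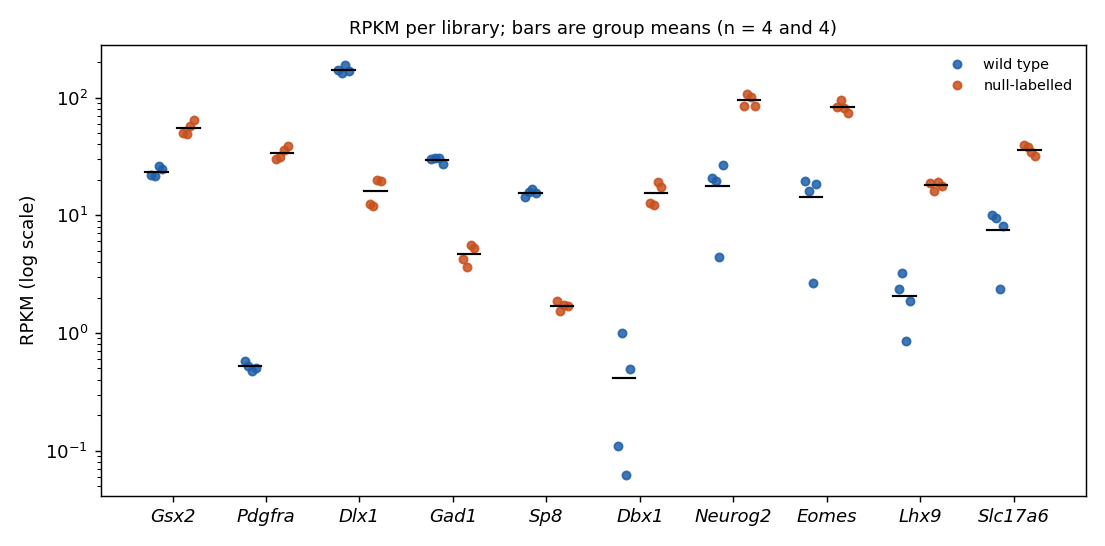
RPKM (log scale) of 10 genes in each of the 4 wild-type (blue) and 4 null-labelled (orange) libraries, with bars at the group means. Gsx2 and Pdgfra are higher in every null-labelled library, Dlx1, Gad1 and Sp8 are lower in every one, and the lowest wild-type point of Eomes (2.64) is library 7.

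Genes of subpallial GABAergic progenitors and neurons fell nearly as a block. Of 12 members tested, 11 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -2.41. Dlx5 dropped from 58.0 ± 5.02 to 7.42 ± 1.68 RPKM and Dlx6 from 22.1 ± 2.64 to 3.74 ± 0.702. Gad1 and Gad2, which make GABA from glutamate, had log2 fold changes of -2.43 ± 0.10 and -2.40 ± 0.11, and the vesicular GABA transporter Slc32a1 one of -2.36 ± 0.18. The homeobox gene Vax1 was lower too (-2.26 ± 0.10). Gsx1, the paralogue of Gsx2, was the member that rose, from 0.994 ± 0.0906 to 2.23 ± 0.680 RPKM (0.67 ± 0.14, adjusted p = 0.00485). The list as a whole was lower by camera (adjusted p = 8.65e-13, adjusted p = 0.206 with an estimated correlation). Dlx6os1 (-3.14 ± 0.14) is annotated on the strand opposite Dlx6 and overlaps it; whether the counting used strand is not given in the sources used here, so reads of overlapping Dlx genes and their antisense RNAs cannot be told apart.

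Striatal genes fell by smaller amounts. Among 18 tested members 13 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.57; camera gave an adjusted p = 5.42e-07 for lower expression and adjusted p = 0.206 with an estimated correlation. The zinc finger gene Zfp503 dropped from 26.3 ± 3.05 to 5.93 ± 1.32 RPKM (-1.99 ± 0.13) and the homeobox gene Six3 from 26.5 ± 2.60 to 10.7 ± 2.25 (-1.25 ± 0.12). Isl1, a LIM homeobox gene, and Ebf1 had log2 fold changes of -1.26 ± 0.13 and -0.93 ± 0.10. The members that rose were Ppp1r1b, which encodes DARPP-32 (0.73 ± 0.12), and Foxp2 (0.55 ± 0.13). Bcl11b stood at 48.9 ± 9.66 RPKM in wild type and 41.0 ± 2.02 in null-labelled libraries (adjusted p = 0.181).

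In the list of the dorsal LGE and olfactory bulb interneurons, 3 of 9 tested genes rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.690). Sp8 dropped from 15.6 ± 1.03 to 1.70 ± 0.132 RPKM, the sharpest fall here, and Meis2 from 115 ± 5.02 to 78.0 ± 4.93 RPKM. Pbx3 (0.40 ± 0.08) and the prokineticin receptor gene Prokr2 (0.63 ± 0.11) rose, as did Foxp2. Tshz1 stood at 18.4 ± 0.801 and 17.8 ± 0.462 RPKM (adjusted p = 0.474) and Etv1 at 4.73 ± 0.592 and 6.08 ± 1.64 RPKM (adjusted p = 0.197). The median was -0.05 (0.03 within libraries 1, 2, 5 and 6) and the mean -0.21, and fry, which asks whether members move one way on balance, gave adjusted p = 7.59e-05 for lower.

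Pallial genes, those of the cortex side of the forebrain, rose. Of 16 pallial progenitor genes tested 12 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone, a median of 1.26 and camera adjusted p = 7.84e-08 (adjusted p = 0.206 with an estimated correlation). Neurog2 rose from 17.9 ± 9.46 to 94.5 ± 11.8 RPKM, Emx2 from 12.6 ± 2.05 to 32.9 ± 2.50, Tfap2c from 4.75 ± 2.28 to 23.6 ± 2.15 and Emx1 from 4.89 ± 2.46 to 17.8 ± 1.45. Pax6 and Tgfa rose by log2 fold changes of 0.84 ± 0.14 and 0.77 ± 0.09. Lef1, a Wnt effector, was the member that fell (-0.65 ± 0.08).

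Pallial glutamatergic neuron genes rose too, with 17 of 19 tested members higher and 0 lower (18 and 0 adjusted over the list alone), a median of 1.79 and camera adjusted p = 1.82e-12 (adjusted p = 0.239 with an estimated correlation). Eomes, the gene of intermediate progenitors, rose from 14.3 ± 7.89 to 83.4 ± 9.21 RPKM, Tbr1 from 31.4 ± 12.6 to 126 ± 7.74, Neurod6 from 38.5 ± 17.8 to 118 ± 13.3 and Slc17a6 from 7.495 ± 3.51 to 35.8 ± 3.39. Nr4a2 rose from 2.16 ± 0.392 to 10.5 ± 0.687 RPKM (1.88 ± 0.09) and Neurod4 by a log2 fold change of 1.90 ± 0.21. Reln stood at 9.12 ± 4.65 and 18.7 ± 8.60 RPKM (adjusted p = 0.109) and Trp73 at 1.31 ± 0.939 and 2.29 ± 1.07 RPKM (adjusted p = 0.264). The wild-type spread came mostly from library 7, in which Eomes stood at 2.64 RPKM against 16.1 to 19.7 in the other wild-type libraries. Without library 7, 17 of 19 of these genes and 12 of 16 pallial progenitor genes passed as higher, with medians of 1.40 and 0.98.

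**Figure D2:**
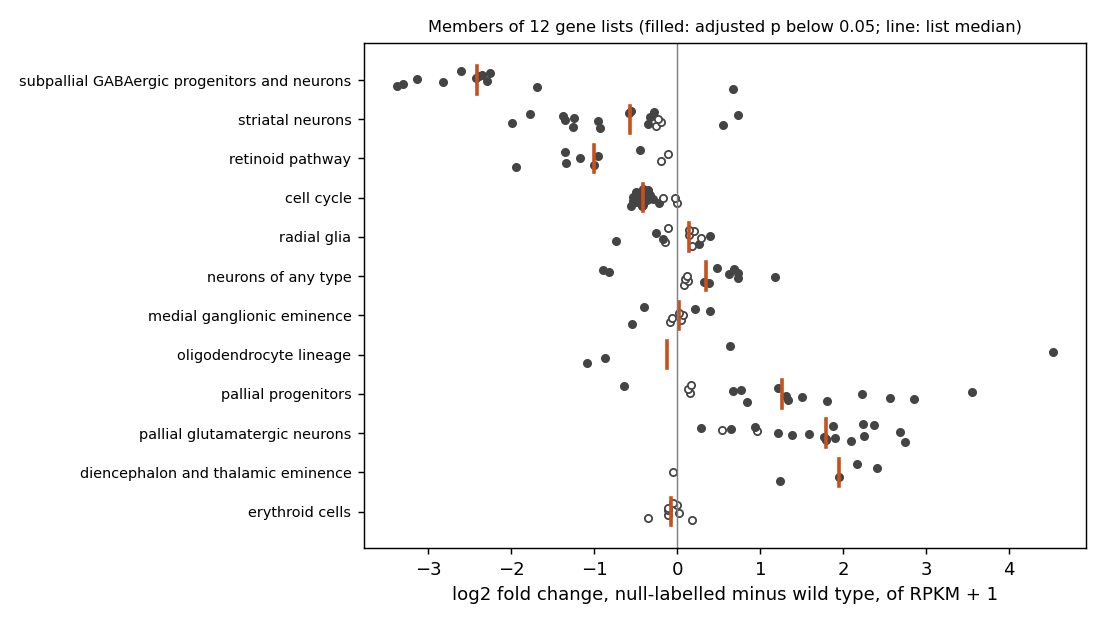
Log2 fold change (null-labelled minus wild type, of RPKM + 1) of each tested member of 12 gene lists; filled points passed an adjusted p of 0.05, open points did not, and orange lines are list medians. Medians run from -2.41 for subpallial GABAergic genes to 1.95 for genes of the diencephalon and thalamic eminence.

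Genes of neighbouring regions were mixed. In the list for the diencephalon and thalamic eminence 4 of 5 tested genes rose and 0 fell, also adjusted over the list alone (median 1.95, camera adjusted p = 0.000341, adjusted p = 0.206 with an estimated correlation). Barhl2 rose from 3.16 ± 1.34 to 19.97 ± 1.35 RPKM, Lhx5 from 0.925 ± 0.576 to 6.30 ± 1.54 and Lhx1 from 0.363 ± 0.215 to 2.21 ± 0.455. Otp, a homeobox gene of the hypothalamus and amygdala, had 0, 1, 0 and 1 reads in the wild-type libraries and 85, 60, 116 and 127 in the null-labelled ones (adjusted p = 1.45e-05). In the medial ganglionic eminence list 2 of 9 rose (Cxcr4 0.40 ± 0.06, Sox6 0.22 ± 0.07) and 2 fell (Lhx6 -0.54 ± 0.14, Zeb2 -0.40 ± 0.05), the same adjusted over the list alone, with camera adjusted p = 0.997. In the caudal ganglionic eminence list 3 of 5 rose (Nr2f1 0.77 ± 0.15, Cck 0.91 ± 0.24, Calb2 1.71 ± 0.48) and Prox1 fell (-0.99 ± 0.11), the same adjusted over the list alone (camera adjusted p = 0.645). The single tested gene of the choroid plexus and cortical hem list, Otx2, fell (-0.50 ± 0.15, adjusted p = 0.0348, also adjusted over the list alone). Sox6 lost its call under each of the 3 other scalings of the libraries (adjusted p = 0.0511 to 0.0523) and without any 1 of libraries 1, 5, 6, 7 or 8 (0.0775 to 0.0974). Calb2 lost it without any 1 of libraries 5, 6, 7, 8 or 12 (adjusted p = 0.0526 to 0.0678) and under a robust fit (0.0789), which left 2 caudal genes higher, and Otx2 without any 1 of libraries 1, 2, 6, 7 or 11 (0.0715 to 0.0890).

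Cell cycle genes fell together by small amounts. Of 25 members 22 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -0.42; camera gave adjusted p = 2.36e-11, and adjusted p = 0.341 with an estimated correlation. Top2a dropped from 202 ± 9.27 to 137 ± 7.66 RPKM (-0.56 ± 0.06), Mki67 from 87.3 ± 2.81 to 64.8 ± 4.63 (-0.43 ± 0.06) and the mitotic kinase gene Bub1 from 30.2 ± 1.29 to 21.1 ± 1.15 (-0.50 ± 0.05). Ccnb1 and Ccne2 had log2 fold changes of -0.44 ± 0.05 and -0.48 ± 0.06. Ccnd1 stood at 100.1 ± 9.29 and 99.7 ± 5.81 RPKM (adjusted p = 0.975). Among 8 cell cycle exit genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.104), led by the cyclin-dependent kinase inhibitor gene Cdkn1c, from 20.8 ± 4.54 to 64.7 ± 5.35 RPKM (1.61 ± 0.13). Cdkn1a (0.33 ± 0.09) and Cend1 (0.25 ± 0.08) were the others. Cdkn1a lost its call without any 1 of libraries 7, 8, 11 or 12 (adjusted p = 0.0514 to 0.0572) and Cend1 without any 1 of libraries 2, 5, 7, 11 or 12 (0.0537 to 0.107). Without any 1 of libraries 7, 11 or 12, 1 of the 8 exit genes passed as higher.

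Radial glia genes went both ways, with 2 of 12 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.690). Sox2 dropped from 175 ± 2.42 to 105 ± 9.35 RPKM (-0.74 ± 0.06) and Nr2e1 from 66.5 ± 3.34 to 55.4 ± 5.36 RPKM, whereas the glutamate transporter gene Slc1a3 rose from 33.2 ± 2.21 to 43.8 ± 2.41 RPKM (0.39 ± 0.06) and the intermediate filament gene Vim from 488 ± 49.2 to 585 ± 29.6 RPKM (0.27 ± 0.08). Vim lost its call without any 1 of libraries 2, 6, 7, 8, 11 or 12 (adjusted p = 0.0587 to 0.107), and Nr2e1 without library 7 (0.0621), when 1 radial glia gene passed as higher and 1 as lower. Of 14 genes expressed in neurons of any type 8 rose and 2 fell, the same adjusted over the list alone (median 0.35, camera adjusted p = 0.00156, adjusted p = 0.465 with an estimated correlation). Elavl4 (0.73 ± 0.07), Rbfox3 (1.18 ± 0.15), Mapt (0.69 ± 0.10) and Gap43 (0.73 ± 0.12) rose. The neurofilament genes Nefm (-0.89 ± 0.17) and Nefl (-0.83 ± 0.18) fell.

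Retinoid pathway genes fell in 7 of 9 cases with 0 rises, also adjusted over the list alone (median -1.01, camera adjusted p = 5.35e-06, adjusted p = 0.206 with an estimated correlation). Aldh1a3, which makes retinoic acid, dropped from 6.08 ± 1.13 to 0.883 ± 0.509 RPKM (-1.94 ± 0.19). The receptor genes Rara (-1.18 ± 0.09), Rarb (-0.95 ± 0.14) and Rxrg (-1.36 ± 0.14) fell too. In the Notch list 5 of 18 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.407). Lfng (-0.71 ± 0.06), Hes5 (-0.58 ± 0.07) and Hey1 (-0.53 ± 0.06) fell along with the ligand gene Dll1 (-0.39 ± 0.04), and the ligand gene Jag1 rose (0.59 ± 0.05).

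Wnt, Hedgehog and FGF lists did not pass camera. Of 12 Wnt genes 7 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.264), among them Wnt7b (1.21 ± 0.22), Rspo3 (0.85 ± 0.14), Nkd1 (0.77 ± 0.13) and Dkk3 (0.75 ± 0.11) upward and Lef1 (-0.65 ± 0.08) downward. Without any 1 of libraries 1, 5, 6, 7, 8 or 11 the number of Wnt genes past the threshold as lower was 2. Of 9 Hedgehog genes 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.128, against 0.00878 for higher from fry): Gas1 from 10.9 ± 1.21 to 22.7 ± 4.05 RPKM, Boc (0.38 ± 0.07) and Cdon (0.58 ± 0.15). Cdon lost its call without library 7 (adjusted p = 0.0528). Ptch1, a readout of Hedgehog signalling, stood at 13.3 ± 1.62 and 12.2 ± 0.737 RPKM (adjusted p = 0.394). Of 9 FGF genes 3 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.315), with Fgfr3 (0.43 ± 0.08), Spry2 (0.35 ± 0.09) and Fgfr1 (0.23 ± 0.04) higher and Fgfr2 (-0.30 ± 0.06) lower.

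The oligodendrocyte lineage list split. Pdgfra (4.52 ± 0.08) and Lhfpl3 (0.64 ± 0.14) rose, while Olig1 dropped from 1.81 ± 0.264 to 0.318 ± 0.0752 RPKM (-1.09 ± 0.09) and Olig2 from 22.3 ± 1.72 to 11.8 ± 2.11 RPKM (-0.88 ± 0.11). All 4 tested members passed, also adjusted over the list alone. The median of the list (-0.12) and its mean (0.80) differed in sign, but the median was 0.04 at a pseudocount of 0.1 and 0.08 with voom, and camera gave adjusted p = 0.812 against 4.89e-05 from fry.

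Pdgfra lies beside Gsx2, on chromosome 5 from 75152292 to 75198215. Of 11 tested genes listed as neighbours of Gsx2, 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.451, against 0.000450 for higher from fry; median -0.04, or 0.01 without library 1, and mean 0.51). Besides Pdgfra, the receptor tyrosine kinase gene Kit (0.95 ± 0.17), Rasl11b (0.56 ± 0.13) and Chic2 (0.34 ± 0.08) rose, and Fip1l1 (-0.20 ± 0.05) and Kdr (-0.22 ± 0.06) fell. Gm19583, a long noncoding RNA gene annotated from 75110321 to 75147107 between Gsx2 and Pdgfra and chosen after its values were seen, had 1, 0, 1 and 0 reads in the wild-type libraries and 62, 65, 48 and 56 in the null-labelled ones. Clock, Tmem165, Srd5a3, Scfd2 and Usp46 did not pass, with log2 fold changes from -0.14 to 0.02.

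**Figure D3:**
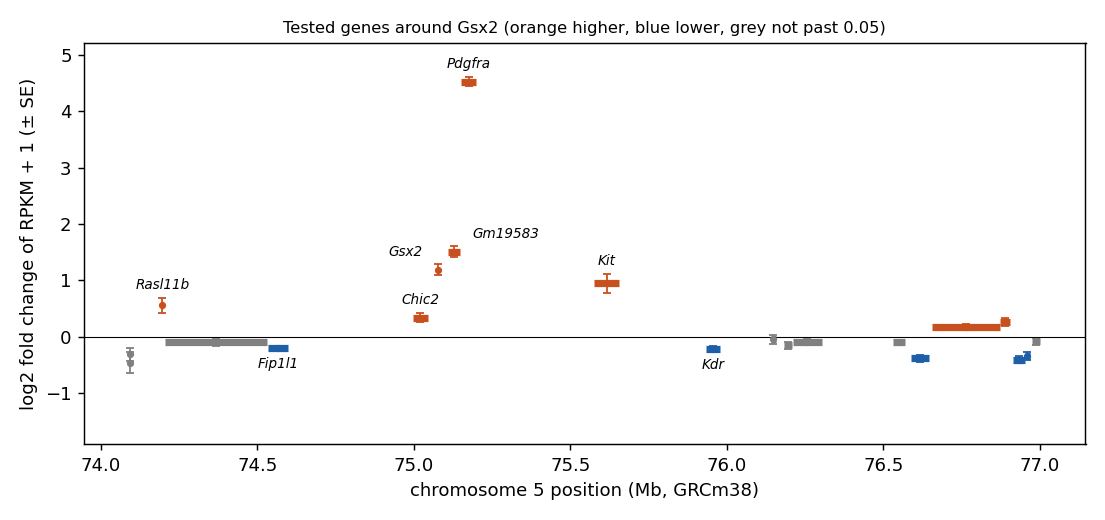
Log2 fold change (of RPKM + 1) ± SE of each tested gene against its position on chromosome 5 (Mb, GRCm38); orange genes were higher and blue genes lower in null-labelled libraries, grey genes did not pass an adjusted p of 0.05, and thick lines span the gene. Pdgfra stands at 4.52, Gm19583 at 1.51 and Gsx2 at 1.19 on this scale, which understates the change of Gm19583 because its RPKM is low.

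Among genes of other cell types, those of endothelium were lower in 5 of 10 cases and higher in 0 (6 and 0 adjusted over the list alone; median -0.26, camera adjusted p = 0.00679, adjusted p = 0.423 with an estimated correlation), with Egfl7 at -0.30 ± 0.06, Tie1 at -0.36 ± 0.09 and Cdh5 at -0.30 ± 0.07. Pdgfrb (-0.24 ± 0.08) was the member past the threshold among 5 pericyte and meningeal genes, and 0 passed by limma adjusted over the list alone (1 at an unadjusted p under 0.05; camera adjusted p = 0.853). It lost its call without any 1 of libraries 1, 5, 6, 7, 8 or 12 (adjusted p = 0.0852 to 0.107). C1qc (0.44 ± 0.10) was the member that rose among 7 microglial genes, also adjusted over the list alone (camera adjusted p = 0.315); without library 6, 2 passed as higher. Of 8 erythroid genes 0 passed by limma, also adjusted over the list alone and at an unadjusted p under 0.05 (camera and fry adjusted p = 0.853 and 0.844); Hbb-y stood at 1171 ± 333 and 1065 ± 196 RPKM (log2 fold change -0.12 ± 0.19, adjusted p = 0.686), and Hba-x at 211 ± 49.96 and 208 ± 33.5 RPKM (adjusted p = 0.976). Haemoglobin genes have near-identical copies, so their single values are uncertain.

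Of the genes that follow sample handling, Jun rose (0.36 ± 0.06) among 3 tested immediate early genes, also adjusted over the list alone (camera adjusted p = 0.351), and Egln3 (0.43 ± 0.09) among 7 hypoxia and glycolysis genes, also adjusted over the list alone (camera adjusted p = 0.315, against 0.0399 for higher from fry). Of the sex-linked and the mitochondrial list 0 members were listed, so neither was tested.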

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

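The tests of explanations in this part were chosen after the result was seen, although the fits without each library and with an estimated correlation were planned. Among 248 groups of 4 libraries, for named genes and list means, 16 held a library far from the other 3 by Dixon's test; chance alone marks about 1 in 20 groups, or 12.4 here. Wild-type library 7 accounted for 9 of the 16. In it Eomes stood at 2.64 RPKM (16.1 to 19.7 in the other wild-type libraries), Barhl2 at 1.19 (3.54 to 4.08), Nhlh1 at 1.10 (5.53 to 6.56), Slc17a6 at 2.38 (8.08 to 10.1), Nrn1 at 1.90 (7.07 to 7.92), Neurod4 at 0.142 (1.15 to 1.40) and Tgfa at 0.962 (1.43 to 1.48). The mean log2(RPKM + 1) of the pallial progenitor list was 2.28 there, against 2.91 to 3.00. Slc18a2, a gene that fell in the null-labelled libraries, was highest in library 7 at 45.3 RPKM (37.1 to 38.3).

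In wild-type library 8, Gad1 stood at 27.1 RPKM (29.96 to 30.4 in the others) and Dll1 at 29.0 (30.5 to 30.8). Kdr was 4.86 RPKM in null-labelled library 5 (5.48 to 5.61), and Nhlh2 13.9 in null-labelled library 6 (15.3 to 15.4). In null-labelled library 12, Rxrg stood at 0.178 RPKM (0.231 to 0.235), Cxcr4 at 13.5 (12.2 to 12.4) and the mean log2(RPKM + 1) of the FGF list at 3.47 (3.38 to 3.39).

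The pattern to weigh is the lower subpallial and higher pallial RNA in the null-labelled libraries, beside a wild-type library that itself held little pallial RNA. Low pallial RNA in library 7 alone was not its source, since pallial glutamatergic neuron genes passed camera as higher without that library (adjusted p = 1.19e-20). With any 1 library left out, camera gave adjusted p = 1.19e-20 to 2.67e-11. On all 8 libraries with an estimated correlation it gave 0.239. More pallial tissue in the null-labelled dissections was weighed as the whole cause of the falls. It would lower subpallial genes by about 1 factor as far as pallial tissue lacks them. Their log2 fold changes had an SD of 1.06 against a median SE of 0.13, or 0.51 against 0.13 without Gsx1, which rose. However, the log2(RPKM + 1) scale spreads a common factor over genes of different RPKM. The pallial levels of these genes are also not known here, so this spread does not decide on more pallial tissue. For the rises (median 1.26 for pallial progenitor genes) such tissue cannot be told apart from a change within LGE cells, because no library of pallial tissue gives the ratios to compare. The altered Gsx2 alleles, the difference the genotypes name, stay open as a biological explanation that was not tested apart from tissue.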

How the results depend on the processing

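The fits by library number and the filter at 5 RPKM were chosen after the data were seen; all others were planned. Gsx2 stayed higher and past the threshold in all 22 alternatives (log2 fold change 1.07 to 1.247). The count of 3242 genes ran from 2471 (without wild-type library 7) to 2954 when 1 library was left out, and from 3222 to 3621 under the other scalings, filters (except 5 RPKM, 2558), voom, the robust fit and the pseudocounts. The covariate for library number gave 3578. Genes with an absolute log2 fold change of at least 1 numbered 208, but 388 with voom, 363 at a pseudocount of 0.1 and 85 at 5, as the pseudocount sets the scale. Testing against a log2 fold change of 0.5 left 205 genes, 113 higher and 92 lower, by construction. Libraries 1, 2, 5 and 6 alone gave 1949 genes with 753 higher, and libraries 7, 8, 11 and 12 alone 2966 with 1052 lower; fewer libraries enter, and the cause of the opposite skews was not tested. The difference of numbers 7 to 12 minus 1 to 6 in wild type and that in null-labelled libraries had a Pearson correlation of 0.307 across genes, which are not independent replicates. No other pairing of libraries was compared, so this value alone does not show that the genotypes shared a difference by library number. With an estimated correlation the lists for subpallial GABAergic, striatal and pallial progenitor genes gave adjusted p = 0.206 each and pallial glutamatergic neurons 0.239, since the estimate widens the test for correlated members. By fry, which asks another question, 5 lists passed that had not passed camera: dorsal LGE (7.59e-05), oligodendrocyte lineage (4.89e-05), neighbours of Gsx2 (0.000450), Hedgehog (0.00878) and hypoxia and glycolysis (0.0399). No result turned its direction past the threshold in any of the alternatives run. Named genes kept their side of the threshold in 2063 comparisons and lost it in 70, of which 18 and 10 fell to the 2 subsets of library numbers and 9 to the fit without wild-type library 7. Over 279 list members and further genes, the 3 other scalings turned 0 directions. Sox6 (adjusted p = 0.0511 to 0.0523) and Notch3 (0.0522 to 0.0853) lost their calls under all 3. Sox9 and Axin2 lost theirs under at least 1, and Ptn, Cdk4, Btg2, Nrarp and Esam gained a call under all 3. No paired analysis was possible because the columns carry no replicate numbers. The planned edgeR and DESeq2 tests were left out because the deposited unit is RPKM, so of the tests for counts voom alone was run on the recovered reads; the Y-gene covariate was not run because 0 such genes are listed. Of the 35 splits of the 8 libraries into 4 and 4, only that by genotype gave as many as 3242 genes. The highest other gave 2. Every other split mixed the genotypes in both groups, which widens the spread within groups, so its low count does not measure chance. A share of 1 in 35 is also the smallest these splits can give, so they cannot exclude chance. Whether all splits are equally likely is left open by a possible difference by library number.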

Other observations

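Genes in this paragraph and the next were chosen after their values were seen, as were the tests of explanations that follow, except the test of scaling for Gsx2. Robo3, a receptor of commissural axons, rose from 4.38 ± 2.65 to 20.3 ± 2.86 RPKM (log2 fold change 2.12 ± 0.31), the netrin receptor gene Dcc from 14.7 ± 3.04 to 38.2 ± 1.23 (1.35 ± 0.12), the semaphorin receptor gene Plxna4 from 9.73 ± 3.32 to 28.98 ± 3.33 (1.53 ± 0.19) and Cntn2, which encodes the adhesion protein TAG-1, from 14.4 ± 4.29 to 43.8 ± 2.08 (1.58 ± 0.17). Nrp2 (1.42 ± 0.31), Sema3c (1.21 ± 0.14) and Nrcam (1.18 ± 0.11) rose as well. Among Ebf genes, Ebf1 fell (-0.93 ± 0.10) while Ebf2 (1.54 ± 0.23) and Ebf3 (2.10 ± 0.22) rose. The transcription factor genes Prdm8 (1.71 ± 0.28), Prdm12 (2.05 ± 0.26), Tfap2a (1.17 ± 0.09) and Tfap2d (1.13 ± 0.19) also rose.

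Abat, which breaks down GABA, dropped from 23.2 ± 1.26 to 10.7 ± 0.789 RPKM (log2 fold change -1.05 ± 0.06). The synaptic adhesion gene Nrxn3 dropped from 12.4 ± 0.978 to 3.06 ± 0.554 RPKM (-1.73 ± 0.10), Fgf3 from 2.56 ± 0.175 to 0.295 ± 0.197 (-1.47 ± 0.11) and Th, the enzyme of dopamine synthesis, from 3.87 ± 1.249 to 1.32 ± 0.370 (-1.05 ± 0.18). The antisense genes Dlx1as (-1.78 ± 0.21), Dlx6os2 (-2.11 ± 0.17) and Six3os1 (-1.59 ± 0.09) fell as well. Each overlaps a homeobox gene on the opposite strand (Dlx1, Dlx6 and Six3), and as the use of strand in counting is not given in the sources used here, their reads and those of these genes were not separated with certainty.

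Beside Gsx2, RNA of Pdgfra, Gm19583, Kit and Chic2 was higher in the null-labelled libraries. Kit starts 499 kb from Gsx2 and, like pallial genes, was low in wild-type library 7 (4.19 RPKM, against 7.36 to 8.65 in the other wild-type libraries). For Kit a change of tissue was therefore not separated from an effect at the locus. More cells of the oligodendrocyte lineage would add Olig1 and Olig2 RNA. Both fell (-1.09 ± 0.09 and -0.88 ± 0.11), whereas Lhfpl3 of the same list rose (0.64 ± 0.14), and only 4 of its 11 members were tested. In wild type Olig2 stood at 22.3 RPKM with Pdgfra at 0.520, so Olig2 RNA was present there with little Pdgfra RNA. A fall of that RNA could hide a rise from added cells, so these values cannot decide. The nearest 2 tested genes on each side of Gsx2 (Fip1l1, Chic2, Gm19583 and Pdgfra) had a median log2 fold change of 0.93, above 99.9556% of such sets around 11254 other genes. That decides nothing because 3 of the 4 are the pattern itself. The nearest 4 outside the pattern (Scfd2, Fip1l1, Kdr and Srd5a3) had a median of -0.15, at percentile 8.77. These were reached by leaving out genes seen to rise, so their low median follows from the choice and decides nothing either. An effect of the altered alleles on their neighbours and loss of repression by Gsx2 protein acting on these genes cannot be told apart, because every library with a rise in Pdgfra (4.52) carries altered alleles and lacks, by its label, the protein. Both stay open as hypotheses, as do more cells of the oligodendrocyte lineage and, for Kit, more pallial tissue.

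Gsx2 RNA itself was higher in the libraries labelled null. Labels swapped between the groups would make the subpallial GABAergic genes higher there if loss of Gsx2 lowers them, and 91.7% of tested members were lower. That premise was not tested apart from the labels, so these values do not decide on a swap. Scaling was not the source, as the lowest log2 fold change under 3 other scalings was 1.197. Transcripts still made from the altered alleles are a candidate explanation that these values cannot decide, because a log2 fold change of 1.19 over the whole gene holds no read positions.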
